A study of Mus musculus with 6 samples.

How the data were processed

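The samples were WEHI-279 mouse lymphoma cells expressing FLAG-tagged PU.1 or Spi-B, with 2 anti-FLAG ChIP libraries and 1 input library per factor, grouped by the factor and sample type given in the labels. The labels differ on how the constructs were introduced, naming retroviral vectors in the design text and stable transfection in the treatment protocol. Per the submitters' processing notes, reads were aligned with Bowtie to mm9. Per the file headers and peak names, peaks were called with MACS, separately for each library in the 4 library lists. The versions, the settings and the use of the input libraries are not given in the sources used here. Per the design text, the libraries were sequenced at different cores and those of each factor were combined with mmChIP into the 2 combined lists. The track lines of both libraries numbered 1 carry the number 75 and those of both numbered 2 carry 100. No source says what these stand for or which core sequenced which library, so the replicate number was treated as a possible batch and values within each number are printed beside the pooled ones for the shared percentages and the chromosome shares. The score comparisons and factor-only counts use the combined lists and have no values within a number.

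The deposited value used for each peak was the score that the authors' peak caller gave it, with a minimum near 50 in every list. No source states its formula. It was used only to rank, split or describe peaks within a list, since lists of different length and depth need not share a scale. Peak lists hold no read counts, so the depth of each library is unknown. A threshold applied to libraries of different depth returns lists of different length, and this moves any share of overlapping peaks. No list held overlapping peaks of its own, and no column of another series was present.

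Overlaps were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A peak counted as shared when at least 1 bp lay in a peak of the other list. Shares carry exact Clopper-Pearson 95% intervals, and were set against 1000 random placements in which each peak moved by 20 to 200 kb up or down (one-sided). The Jaccard index in base pairs was computed for the 6 pairs of libraries, and the within-factor minus between-factor difference was tested by exact permutation over the 3 splits, which cannot reach p = 0.05. Scores of shared and other peaks of a combined list were compared by the probability that a shared peak scores higher, with 100000 permutations. Factor-only peaks were combined peaks that met neither the other combined list nor either library of the other factor. Chromosome shares were compared with Fisher's exact test and Benjamini-Hochberg adjustment over 20 chromosomes. The chromosome tests, the counts of merged regions and the tests on chromosome 11 were chosen after the data were seen.

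The tests above other than those, the alternatives named as planned and the rule for named regions were set before the data were examined. The rule took the 5 shared combined peaks with the best mean rank of score over both lists and the 5 highest-scoring factor-only peaks of each combined list. Its parts on the genes of the expressed proteins and on gene lists needed an annotation of the files' build and were left out. For the same reason the planned promoter shares, 14 gene lists and 14 motifs were not run, since no mm9 genome or annotation was used here and the lists name no genes. Positions are given in mm9, counted from 1.

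The overlap code was tested on simulated lists made from the 4528 combined PU.1 peaks. True shares of 10, 40 and 70% were found as 10.7, 39.9 and 69.5%. The total number of overlapped peaks equalled that of bedtools 2.31.1 for each share, and calls were not compared peak by peak. Of 100 simulated lists placed at random, 2 had a p at or under 0.05. Alternatives covered the overlap criterion (50% of the shorter peak, midpoints within 100 bp, peaks widened by 500 bp), the upper part of each list by score, lists of equal length, placement anywhere on the chromosome, peaks present in both libraries, each library left out in turn and the replicate number as a block. Alternatives added later left out chromosome 11, or the 11 windows of 1 Mb with at least 25 peaks in a library numbered 1 together with unplaced sequence.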

Results

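PU.1 and Spi-B are related ETS-family transcription factors that act in the B cell lineage. The study mapped where each of them bound the genome of WEHI-279 cells, a mouse lymphoma cell line made to express a FLAG-tagged form of either factor. Chromatin was precipitated with an anti-FLAG antibody and sequenced (ChIP-seq), so bound regions appear as peaks of aligned reads. There were 2 ChIP libraries for PU.1, 2 for Spi-B and 1 input library for each factor. The input libraries are not analysed here. PU.1 replicate 1 had 6621 peaks and PU.1 replicate 2 had 21120, covering 3.92 and 12.9 Mb. Spi-B replicate 1 had 8210 peaks and Spi-B replicate 2 had 9591, covering 4.22 and 8.48 Mb. The authors' combined lists, made from the libraries of each factor, held 4528 PU.1 peaks (median width 1261 bp) and 3360 Spi-B peaks (median width 1243 bp). Read depth is unknown, so the lengths of the lists could not be set against it. No source says whether the replicates came from separate cultures, so a p-value across them measures only the spread between these libraries, which may be technical.

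The design asked which regions PU.1 and Spi-B had in common and which they did not. A large part of each factor's combined peaks lay at regions of the other factor. Of the 4528 combined PU.1 peaks, 1900 (42.0%, 95% Clopper-Pearson interval 40.5 to 43.4) overlapped a combined Spi-B peak by at least 1 bp. Of the 3360 combined Spi-B peaks, 1899 (56.5%, interval 54.8 to 58.2) overlapped a combined PU.1 peak. Peaks moved at random by 20 to 200 kb overlapped in 0.872% of cases on average for PU.1 and in 1.17% for Spi-B. None of 1000 such placements came near the observed shares, with highest values of 1.37% and 1.73% (one-sided permutation test by placement, p = 0.001 for both, the smallest that 1000 placements can give). Every pair of the lists passed this test in the same way. The samples held no ChIP from cells without a FLAG-tagged factor. The test thus cannot separate binding by both factors from signal common to any such ChIP in these cells. Intervals and p-values here cover counting error over peaks, which are not biological replicates.

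The shares moved with the library that stood for a factor. With PU.1 replicate 2 alone in place of the combined PU.1 list (without PU.1 replicate 1), 13.2% of PU.1 peaks overlapped a combined Spi-B peak, and with Spi-B replicate 1 alone as the Spi-B list (without Spi-B replicate 2) 68.4% of combined PU.1 peaks did. With Spi-B replicate 2 alone (without Spi-B replicate 1), 22.5% of Spi-B peaks overlapped a combined PU.1 peak. Among the libraries numbered 1, 70.5% of PU.1 peaks overlapped Spi-B and 57.2% of Spi-B peaks overlapped PU.1. Among the libraries numbered 2, 4639 of 21120 PU.1 peaks and 47.8% of Spi-B peaks did.

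A smaller group of combined peaks met no list of the other factor. There were 1178 such PU.1-only peaks (26.0% of the combined PU.1 list, interval 24.7 to 27.3) and 472 Spi-B-only peaks (14.05%, interval 12.9 to 15.3). Another 1450 PU.1 peaks (32.0%) and 989 Spi-B peaks (29.4%) were absent from the other combined list and present in a library of the other factor. PU.1 replicate 1 held 32.0% of the PU.1-only peaks and 89.8% of the shared PU.1 peaks, while PU.1 replicate 2 held 95.2% and 94.7%. Both PU.1 libraries held 366 of the PU.1-only peaks (31.1%, interval 28.4 to 33.8), and both Spi-B libraries held 106 of the Spi-B-only peaks (22.5%, interval 18.8 to 26.5). Among shared peaks, 86.6% of the PU.1 peaks and 72.2% of the Spi-B peaks were in both libraries of their factor. A further 121 Spi-B-only peaks (25.6%) were in neither Spi-B library, compared with 45 PU.1-only peaks (3.82%) in neither PU.1 library.

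The factor-only counts rested on the definition used. With midpoints within 100 bp as the criterion for a shared region there were 1899 PU.1-only and 1029 Spi-B-only peaks. Without Spi-B replicate 1 the PU.1-only peaks numbered 1988, and without PU.1 replicate 2 the Spi-B-only peaks numbered 942.

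Shared regions had the higher peak scores in both combined lists. The median score of shared PU.1 peaks was 151, compared with 83.4 for PU.1 peaks absent from the combined Spi-B list and 72.7 for PU.1-only peaks. The median score of shared Spi-B peaks was 130, compared with 77.5 for Spi-B peaks absent from the combined PU.1 list and 72.5 for Spi-B-only peaks. A shared PU.1 peak outscored one absent from the combined Spi-B list with a probability of 0.740, and the corresponding value for Spi-B was 0.707 (two-sided permutation test over peaks, p = 1e-05 for each, the smallest that 100000 permutations can give). Against factor-only peaks the probabilities were 0.803 for PU.1 and 0.749 for Spi-B, with the same smallest p. The score is the authors' own value for each peak and was compared only within a list. Every list begins near a score of 50, so a weak peak can more easily miss the cut in any second list. No matching comparison was made within a factor, so whether the score difference is particular to sharing between factors is not known.

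The shared percentage fell with each decile of the score in both combined lists, except from 18.8% to 20.6% at the last step for PU.1. In the top decile by score, 85.4% of PU.1 peaks and 92.3% of Spi-B peaks were shared, and in the bottom decile of Spi-B 34.5% were. PU.1-only peaks made up 1.77% of the top decile of the PU.1 list (8 peaks) and 50.7% of the bottom decile. Spi-B-only peaks made up 2.38% of the top decile of the Spi-B list (8 peaks) and 24.4% of the bottom decile.

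**Figure D1:**
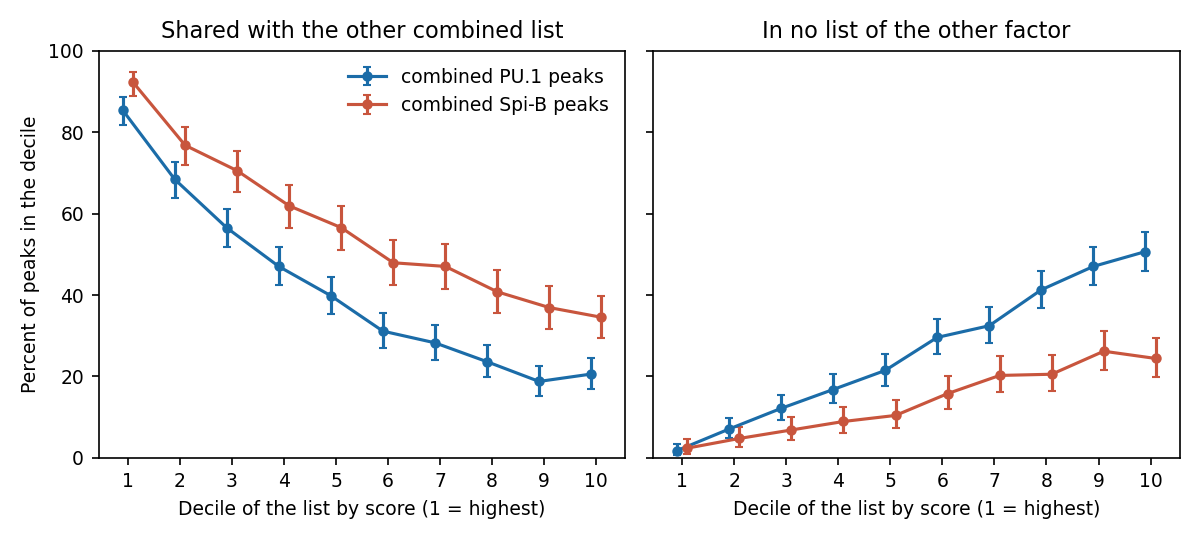
Percent of combined peaks shared with the other combined list (left) and percent in no list of the other factor (right), by decile of each list from the highest score (1) to the lowest (10). Points are PU.1 (blue) and Spi-B (red), and bars are 95% Clopper-Pearson intervals over peaks. The shared percentage goes from 85.4 (PU.1) and 92.3 (Spi-B) in the top decile to 20.6 and 34.5 in the bottom decile.

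The strongest shared region was the same in both combined lists. It lay on chromosome 2 (127833093 to 127835821 in mm9, PU.1 coordinates), ranked 1 by score for PU.1 and for Spi-B, and had a peak in all 4 libraries. The shared regions on chromosome 10 (5743940 to 5745792, rank 6 for PU.1 and 12 for Spi-B) and chromosome 17 (19104753 to 19106186, ranks 5 and 16) were also found in all 4 libraries. The shared region on chromosome 12 (16753550 to 16755865, ranks 17 and 3) was found in PU.1 replicate 1 and Spi-B replicate 1 and in neither library numbered 2. The remaining region of the top 5, on unplaced sequence (Un_random, 5546868 to 5550190, ranks 7 and 2), had no peak in any of the 4 libraries. No mm9 gene annotation was used here, so regions are named by position only.

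The 5 highest-scoring PU.1-only regions were found in both PU.1 libraries and in no Spi-B library. They lay on chromosome 3 (134001578 to 134003084, score 505), chromosome 4 (125155018 to 125156118, score 405), chromosome 8 (99189511 to 99190688, score 392), chromosome 6 (116408103 to 116410652, score 356) and chromosome 2 (178399266 to 178400398, score 350.1). The first of them ranked 107 in the combined PU.1 list. Among the 5 highest-scoring Spi-B-only regions, those on chromosome 9 (89915827 to 89917048, score 387), chromosome 6 (127031346 to 127032601, score 375) and chromosome 10 (125938898 to 125940235, score 354) were found in both Spi-B libraries. The other two, on Un_random (5892608 to 5894870, score 666) and chromosome 12 (75904403 to 75906048, score 519), had no peak in either Spi-B library.

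Libraries of the same factor overlapped far more than random placements did. Of the PU.1 replicate 1 peaks, 72.3% (interval 71.2 to 73.3) overlapped PU.1 replicate 2, and 22.7% of the longer PU.1 replicate 2 list overlapped PU.1 replicate 1. Of the Spi-B replicate 1 peaks, 40.7% (interval 39.6 to 41.8) overlapped Spi-B replicate 2, and 34.6% overlapped in the reverse direction. Random placements reached at most 2.63% for PU.1 replicate 1 and 1.80% for Spi-B replicate 1 (one-sided permutation test by placement, p = 0.001, the smallest possible with 1000 placements). The combined PU.1 peaks were found in PU.1 replicate 1 in 69.9% of cases and in PU.1 replicate 2 in 95.9%. The combined Spi-B peaks were found in Spi-B replicate 1 in 86.6% of cases and in Spi-B replicate 2 in 67.6%.

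On average, libraries of the same factor did not have a higher Jaccard index (shared length over the length covered by either list) than libraries of different factors. The pair with the highest index was PU.1 replicate 1 with Spi-B replicate 1, at 0.414. The PU.1 pair reached 0.176 and the Spi-B pair 0.164, and the other pairs between factors lay between 0.141 and 0.183. With lists of equal length the PU.1 pair reached 0.279, above those other pairs, which lay between 0.142 and 0.251, and the Spi-B pair reached 0.161. The mean of the within-factor pairs minus the mean of the between-factor pairs was -0.0549 (exact permutation test, two-sided p = 1 over the 3 splits of 4 libraries, where the smallest possible p is 0.333). With between-factor pairs of different replicate number only, the difference was 0.00766, so its direction turned. With all pairs it was -0.0194 with lists of equal length and -0.000949 by share of the shorter list. By that share the PU.1 pair stood highest at 72.3% and the Spi-B pair at 40.7%. The between-factor pairs ranged from 40.1% to 70.5%, the latter for PU.1 replicate 1 with Spi-B replicate 1. Lists of unlike length limit the Jaccard index as deposited, as for the PU.1 pair. By share of peaks at equal length, same-factor pairs stood at 53.3% and 37.0%, and between-factor pairs ranged from 31.9% to 63.9%. Each number holds 1 library per factor, so the difference has no value within a number.

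**Figure D2:**
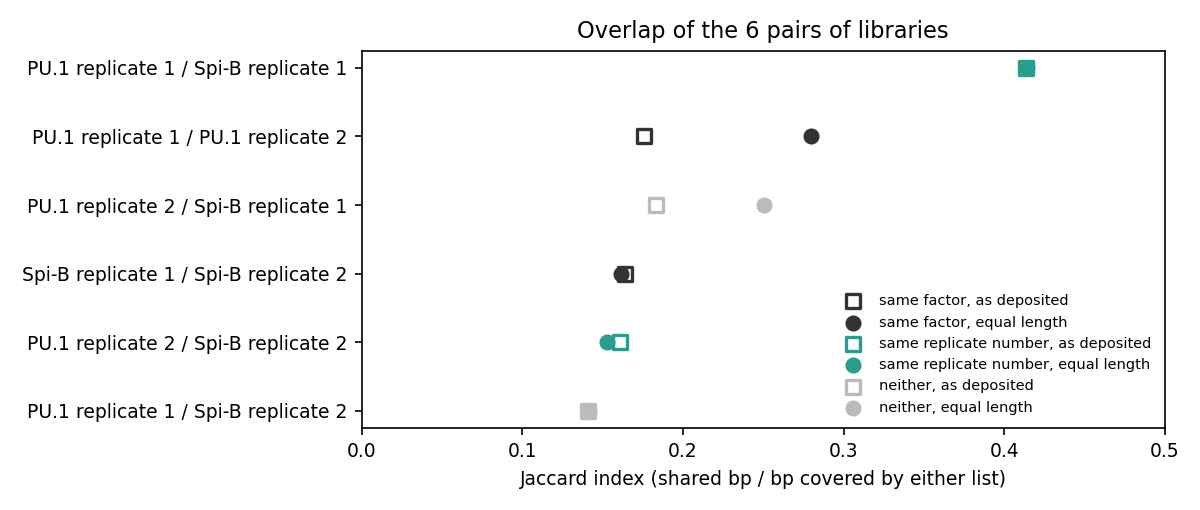
Jaccard index of peak length for the 6 pairs of ChIP libraries, with lists as deposited (open squares) and with each list trimmed to its 6621 highest-scoring peaks (filled circles), 1 value per pair. PU.1 replicate 1 with Spi-B replicate 1 lies highest at 0.414 under both settings, and the within-factor pairs lie at 0.176 and 0.164 as deposited.

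Regions held by exactly 2 libraries were counted by pair, a count chosen after the data were seen. The 4 lists merged into 28974 regions, of which 2208 (7.62%) held a peak of all 4 libraries. Regions held by exactly both libraries of 1 factor numbered 892 for PU.1 and 252 for Spi-B, 1144 together, and the pairs that share neither factor nor number held 1239. Regions held by exactly both libraries of 1 replicate number came to 2251, with 832 for the libraries numbered 1 and 1419 for those numbered 2. With lists of equal length the factors held 656 (PU.1) and 362 (Spi-B), the libraries numbered 1 held 1109, and those numbered 2 held 267, fewer than either factor. The factors then held 1018 together and the pairs that share neither held 482, so the order of these sums turned. PU.1 replicate 2, the longest list, alone held 12941 regions.

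The combined lists differed in how peaks were spread over chromosomes, in tests chosen after the data were seen. Chromosome 11 held 501 combined PU.1 peaks (11.1% of the list) and 177 combined Spi-B peaks (5.27%), an odds ratio of 2.24 (Fisher's exact test, adjusted p = 2.84e-19). Chromosome 14 held 3.78% of combined PU.1 and 6.61% of combined Spi-B peaks (odds ratio 0.555, adjusted p = 1.77e-07), and chromosome 8 held 3.49% and 5.00% (odds ratio 0.687, adjusted p = 0.00722, exact tests). These were the 3 of 20 chromosomes past an adjusted p of 0.05 (Benjamini-Hochberg, two-sided, over peaks). Chromosome Y, with 0 combined PU.1 peaks and 1 combined Spi-B peak, was not among the 20. Of the 20, chromosome X had the fewest peaks per Mb in both lists, 0.504 for PU.1 and 0.474 for Spi-B. Of the 1178 PU.1-only peaks 130 lay on chromosome 11 and 41 on chromosome 14, and of the 472 Spi-B-only peaks 24 and 58 did. These proportions were near those of the whole combined lists, except for Spi-B on chromosome 14, where the proportion lay above 6.61%. The highest density was on chromosome 11 for PU.1 (4.11 per Mb) and on chromosome 19 for Spi-B (2.25 per Mb).

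The chromosome 11 difference was not present in the same form in the libraries. Chromosome 11 held 7.87% of PU.1 replicate 1, 6.97% of PU.1 replicate 2, 7.84% of Spi-B replicate 1 and 11.5% of Spi-B replicate 2. Among the libraries numbered 1 the factors thus stood at 7.87% and 7.84%, and among those numbered 2 Spi-B stood above PU.1, the reverse of the combined lists. On chromosome 14 the Spi-B share was above the PU.1 share among the libraries numbered 1 (6.59% and 5.80%) and below it among those numbered 2 (3.16% and 3.91%). On chromosome 8 the PU.1 share was above the Spi-B share among those numbered 1 (5.51% and 4.64%) and close to it among those numbered 2 (5.29% and 5.36%). The shared fraction of combined PU.1 peaks was 24.2% on chromosome 11 and 44.2% elsewhere (Fisher's exact test, adjusted p = 8.25e-18 over 10 such comparisons of lists, each pair taken in both directions). Such fractions, here and below, depend on how many peaks each list held on chromosome 11. With 501 combined PU.1 and 177 combined Spi-B peaks there, they in part restate the difference in counts. Between PU.1 replicate 1 and Spi-B replicate 1 the corresponding shares of PU.1 peaks were 72.7% and 70.3% (Fisher's exact test, adjusted p = 0.301). Between the libraries numbered 2 the direction was the reverse of that in the combined PU.1 list, with 33.1% of PU.1 peaks overlapping Spi-B on chromosome 11 and 21.1% elsewhere (Fisher's exact test, adjusted p = 2.24e-23). Of the combined Spi-B peaks, 67.2% on chromosome 11 and 55.9% elsewhere were shared (Fisher's exact test, adjusted p = 0.0038). Spi-B replicate 2 peaks overlapped PU.1 replicate 2 in 42.4% of cases on chromosome 11 and in 48.6% elsewhere (Fisher's exact test, adjusted p = 0.000198).

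**Figure D3:**
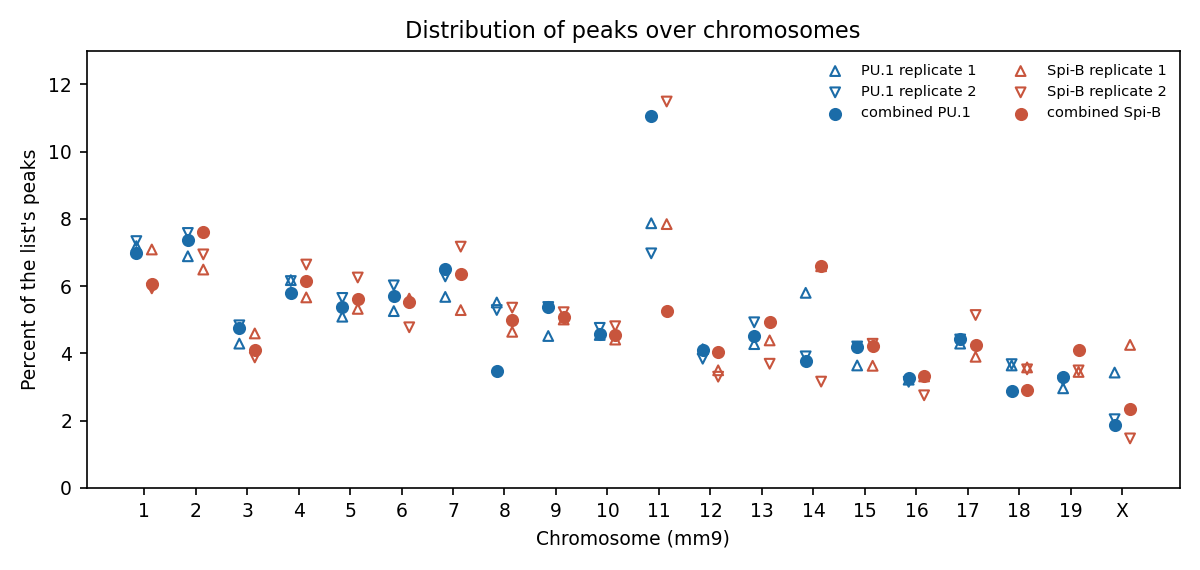
Percent of each list's peaks on each chromosome, for the 4 libraries (open triangles, up for replicate 1 and down for replicate 2) and the 2 combined lists (filled circles), PU.1 in blue and Spi-B in red. On chromosome 11 the combined lists stand at 11.1% (PU.1) and 5.27% (Spi-B), while the libraries lie between 6.97% and 11.5%.

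Peaks on chromosome 14 were also concentrated in a single stretch in both libraries numbered 1. The 4 windows of 1 Mb from 42000001 to 46000000 held 151 peaks of PU.1 replicate 1 and 211 of Spi-B replicate 1. The same windows held 22 peaks of PU.1 replicate 2 and 10 of Spi-B replicate 2. In the combined lists they held 4 PU.1 peaks and 43 Spi-B peaks, out of 171 and 222 on the chromosome.

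**Figure D4:**
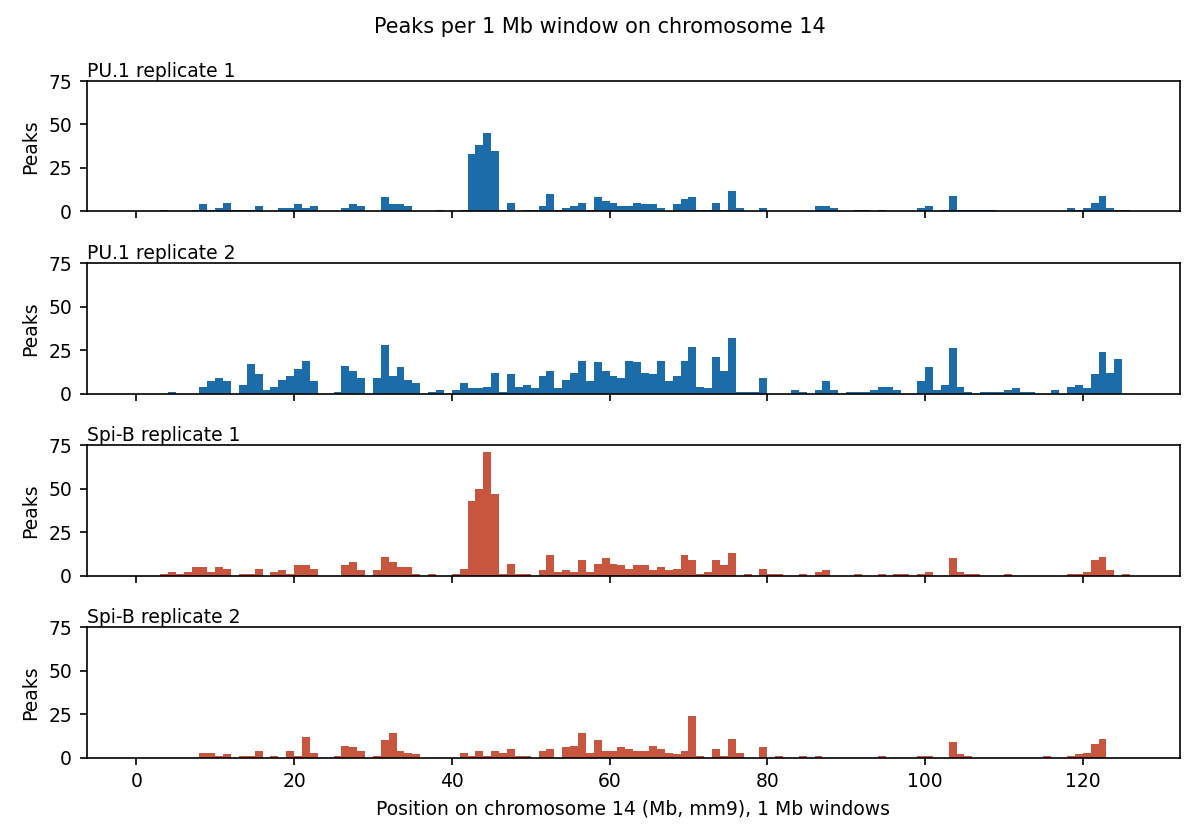
Number of peaks per 1 Mb window along chromosome 14 (mm9) in each of the 4 libraries, PU.1 in blue and Spi-B in red, 1 bar per window. The windows from 42000001 to 46000000 stand out in both libraries numbered 1, with 151 and 211 peaks, and not in those numbered 2, with 22 and 10.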

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

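The alternatives that left out chromosome 11 or the dense windows, the alternatives to the factor-only counts and to the regions in all 4 libraries, and the same-number and equal-length block tests were chosen after the results were seen. The shared percentages of the combined lists stayed above all random placements under 14 alternatives each (13.2 to 68.4% for PU.1 and 22.5 to 78.0% for Spi-B), as did the replicate overlaps under 7 each (53.3 to 76.3% for PU.1 and 28.6 to 42.7% for Spi-B). The score difference kept its direction and its side of the threshold under 2 alternatives per factor, with probabilities of 0.694 to 0.803 for PU.1 and 0.667 to 0.749 for Spi-B. With the replicate number as a block, the shared percentages averaged 46.2% for PU.1 and 52.5% for Spi-B. The within-factor minus between-factor difference reversed under the replicate block with between-factor pairs of different number, to 0.00766 as deposited and 0.0242 with lists of equal length. This follows from leaving out the pair with the highest index, and 4 other alternatives gave -0.118 to -0.000949. The numbers were not taken to pair the libraries, since no source says what the numbers, or the 75 and 100 that go with them, mark, and 2 pairs are too few to tell from the data. The replicate 1 minus replicate 2 differences of the factors correlated at 0.0288 over 28974 regions as deposited. The correlation was 0.125 with lists of equal length and -0.0123 without dense windows and unplaced sequence. These values do not decide the pairing, since regions held by no library were left out. As deposited, 12941 of the regions were held by PU.1 replicate 2 alone and 4528 by Spi-B replicate 2 alone. PU.1-only peaks numbered 1899 with midpoints within 100 bp, 366 when found in both PU.1 libraries, and 1343 to 1988 with a Spi-B library left out. Spi-B-only peaks numbered 1029, 106, and 637 to 942 with a PU.1 library left out. Each of these counts follows from a stricter or looser definition. Regions in all 4 libraries numbered 2172 without dense windows and unplaced sequence and 1508 with lists of equal length. Planned promoter, gene list and motif comparisons were not run, and unknown read depth limits every comparison of list lengths.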

Other observations

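Among the tests below, those of list length, of a batch behind the replicate number and of binding by 1 factor, the counts by window, and the comparisons within score ranges and by chromosome, were chosen only after the results were seen. The margin of 0.05 in the batch test was likewise set after its value was known. The 1 Mb windows richest in shared regions included chromosome 17 from 34000001 to 35000000, with 13 combined PU.1 peaks of which 10 were shared, and 15 combined Spi-B peaks. A window on chromosome 7 (3000001 to 4000000) held 10 PU.1 peaks, 9 of them shared, and 9 Spi-B peaks. The window from 5000001 to 6000000 on the unplaced sequence Un_random held 10 PU.1 peaks, 9 of them shared, and 22 Spi-B peaks.

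Some combined peaks had no peak in any library of their own factor. There were 90 such PU.1 peaks, 23 on unplaced sequence, and 208 such Spi-B peaks, 45 on unplaced sequence. Their median scores were 65.9 for PU.1 and 69.8 for Spi-B, below the 100.4 and 100.5 of the other combined peaks. They also reached the top of the lists, with a best rank of 7 for PU.1 and 2 for Spi-B, and 9 of the 100 highest-scoring Spi-B peaks were of this kind, 8 of them on unplaced sequence.

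PU.1 replicate 1 and Spi-B replicate 1, which share a number and not a factor, had a higher Jaccard index than any other pair of libraries. The index is relative to the length covered by either list and does not rank the pairs by shared length. Unequal list lengths do not account for it, since with 6621 peaks per list the pair kept a Jaccard index of 0.414 and the next pair reached 0.279. Dense peak clusters do not account for it either, since without the dense windows and unplaced sequence the pair stood at 0.429 and the next at 0.188. A shared batch behind each number may be involved, and the test of it cannot decide. The other same-number pair, PU.1 replicate 2 with Spi-B replicate 2, stood at 0.152 with equal lengths. This was below the lower within-factor pair, that of Spi-B, at 0.161 by less than the margin of 0.05, and the difference has no measured spread. Both of these pairs hold Spi-B replicate 2, and a batch confined to the libraries numbered 1 need not make those numbered 2 alike. The dense runs described next also divided by number in both factors. No biological explanation was tested.

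Both libraries numbered 1 held dense runs of peaks that were sparse in both libraries numbered 2. On chromosome 14 from 42000001 to 46000000 lay 2.28% of PU.1 replicate 1 and 2.57% of Spi-B replicate 1 peaks, compared with 0.104% of each replicate 2 list, and 1.28% of combined Spi-B peaks compared with 0.0883% of combined PU.1 peaks, while the X windows held 0.208% and 0.287%. Binding by 1 factor only is argued against by the pattern itself, since the runs were in libraries of both factors. The test of it largely restates this. In 8 windows on 14 and X chosen in Spi-B replicate 1 the share of PU.1 peaks was 17.4 times higher in replicate 1 than in replicate 2 (95% interval, normal approximation on the log ratio, 12.6 to 24.0). In 5 windows chosen in PU.1 replicate 1 that of Spi-B peaks was 18.3 times higher (11.02 to 30.2). The intervals count peaks as independent, although these lie close together in few windows. Reads from a tandemly repeated sequence remain a candidate explanation, tested by pairs of equal distances between peaks (within 50 bp), which were 1.17 to 1.35 times the random mean, above all 1000 placements on chromosome 14 and inside their range on X. This stays open because the next densest 4 windows, away from these clusters, exceeded all placements in Spi-B replicate 1, at 4.49 times the mean, and lay inside their range in PU.1 replicate 1, at 1.25 times (one-sided permutation p = 0.285).

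Chromosome 11 held more of the combined PU.1 list and less of the combined Spi-B list than of the libraries behind them. Of PU.1 replicate 1 peaks also found in replicate 2, 71.7% on chromosome 11 and 64.1% elsewhere were in the combined list (Fisher's exact test, p = 0.00161), while for Spi-B the values were 37.4% and 63.7% (p = 2.26e-19), and other chromosomes also stood apart, with 38.1% on 8 and 77.2% on X for PU.1, and 46.4% (PU.1) and 48.3% (Spi-B) on 18. Peaks found in both libraries made up 67.8% of the combined PU.1 and 60.4% of the combined Spi-B list, so these shares nearly restate the pattern, and whether combining treated chromosome 11 apart stays open. By replicate 1 score, Spi-B peaks above the median were kept in 55.7% of cases on chromosome 11 and 83.7% elsewhere (Fisher's exact test, p = 2.45e-13) and the others in 23.0% and 43.2% (p = 1.22e-07), while for PU.1 the values were 87.1% and 83.6% above the median (p = 0.202) and 56.4% and 44.6% for the others (p = 0.0011). Extra copies of chromosome 11 could lift weak PU.1 peaks past the threshold. They would also be carried by the libraries, where chromosome 11 held 7.87% and 6.97% of PU.1 peaks and 7.84% and 11.5% of Spi-B peaks. This argues against extra copies as the only cause of the 11.1% in the combined PU.1 list. The same shares argue against a difference between the factors as the only cause. They were nearly equal among the libraries numbered 1, and Spi-B stood higher among those numbered 2. A partial role of either stays open. By score, chromosome 11 held 252 of the 2264 lower-scoring combined PU.1 peaks (11.1%) and 249 of the 2264 higher-scoring ones (Fisher's exact test, p = 0.925), which does not decide the role of extra copies.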
